A study of Mus musculus with 12 samples.

How the data were processed

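HSCs of mice aged 2 to 3 months were sorted by the study in lots of 5000 to 7000 cells after subcutaneous injection of 100 µL of corn oil alone or with 2 µg of E2. The labels give amplification with the NuGEN Ovation Pico WTA V2 system, labelling with the Encore Biotin module and hybridisation to the Affymetrix Mouse Gene 1.0 ST array. The deposited values are linear probe set intensity values for 35474 probe sets on 12 arrays. They ran from 0.62 to 16148 with quartiles close together between arrays. The summarisation, background correction, normalization and software behind them, and the duration of the treatment, are not given in the sources used here.

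Probe sets took their gene symbols from the platform's annotation table. Of all probe sets, 21780 had 1 symbol, 1605 several and 12089 none, and only those with 1 symbol entered the comparisons of genes. Entrez identifiers of 21689 probe sets matched the RefSeq gene table (assembly GRCm38.p6, used for names only), which changed 0 symbols. The probe set with the highest mean stood for each of 19935 genes, of which 998 had several probe sets. Values were taken as log2 of the intensity plus 1. Genes were kept when their mean over all arrays was above the median of genes, a log2 value of 7.52 or an intensity of 182, which left 9967. No background level is given with the values, so levels below 182 were treated as close to background.

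Differential expression was tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 12 arrays, with moderated statistics from eBayes (8 residual and 5.38 prior degrees of freedom) and Benjamini-Hochberg adjustment over genes within each comparison. A gene was called at an adjusted p under 0.05. The contrasts were E2 minus oil in males, in females and averaged over the sexes, the female response minus the male response, and female minus male under oil and under E2. Agreement of the sexes was described by correlations across genes and by shared calls against the product of the call rates. Python 3.11.15 with NumPy 2.4.6 and matplotlib 3.10.9 drew the figures.

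Gene lists, 18 of pathways and 10 of cell type markers, were tested with limma's camera at a preset correlation of 0.01, 2-sided, adjusted over the 28 lists within each comparison. Camera with a correlation estimated from the data and the self-contained test fry were alternatives. An exact permutation of list means was added after the result with an estimated correlation had been seen. It used 400 relabellings within strata, with a smallest p of 0.005, whereas 3 arrays against 3 alone allow no p under 0.1.

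The tests, contrasts, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 8 largest called increases and decreases per E2 comparison whose arrays did not overlap (in both sexes for the average), up to 4 members with the smallest p from each described list, and always Esr1, Esr2, Pgr, Greb1, Ccnd1, Myc, Mki67, Cdk1, Cdkn1a, Cdkn1c, Slamf1, Cd48, Kit and Procr. For the sexes it named Xist, Ddx3y, Eif2s3y, Kdm5d, Uty and the 5 largest called differences, and for the difference of responses the 6 genes with the smallest p. Clones, predicted genes and small RNA genes were counted but not named. Further list members that were called, Arntl, and Ccr2, S100a8 and S100a9 among the markers, were named after their values had been seen.

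The alternatives were quantile normalization, median centring, an offset of 16, no filter or a filter at the 25th percentile, the mean of a gene's probe sets, eBayes with trend and robust estimation, array weights, a fit of the compared groups alone, an absolute log2 fold change of at least 1, an adjusted p of 0.1, a block for the replicate number, and each array left out in turn. A fit that leaves out an array keeps 2 in its group and pools the spread of all groups.

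The steps were tested on simulated data with 200 changed genes among 9967. For E2 in males, the share recovered was 10% at a log2 change of 0.3, 68% at 0.5, 94% at 1 and 100% at 2, with 7 false calls among 143. For the averaged effect it was 40%, 90%, 98% and 100% at the same changes, counted without regard to sign, with 9 false calls among 173. The simulated genes were independent and had the same spread in all groups. The rates therefore do not cover correlated genes or the wider spread of the female E2 arrays. E2 in females alone was not simulated.

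Probe sets with several symbols or none were left out of the genes, since they cannot be assigned to 1 gene, and were tested separately. The outlier test needs groups of at least 4 samples and was not run on groups of 3. No array was removed.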

Results

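Gene expression was measured on 12 arrays of mouse hematopoietic stem cells (HSCs), the bone marrow cells from which all blood lineages arise. The cells were sorted as CD150+ CD48- c-kit+ Sca-1+ lineage- from male and female mice given corn oil or 2 µg of estradiol (E2), the main estrogen. The 4 groups were oil-treated males, E2-treated males, oil-treated females and E2-treated females, each group from 3 mice with 3 arrays. The median intensity per array lay between 143 and 159, and the upper quartile between 368 and 385. The number of arrays limits the precision of each value. Xist, the RNA that silences an X chromosome, read 61.9 to 73.0 on the male arrays and 3417 to 3897 on the female arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty read 247 to 803 in males and 19.1 to 48.5 in females, so all 12 arrays matched their sex labels. After the filter on dim genes, 9967 genes were tested.

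The first comparison set E2 against oil in males. Thbs1, which encodes the matrix glycoprotein thrombospondin 1, rose from an intensity of 95.5 ± 6.72 to 1092 ± 389 (mean ± SD, n = 3). Itgam, the CD11b integrin chain of myeloid cells, rose from 113 ± 44.3 to 1046 ± 391. Chad, a matrix protein that binds integrins, rose from 228 ± 11.8 to 1485 ± 399. Among genes that fell, Nkg7, a granule membrane protein of cytotoxic cells, went from 573 ± 131 to 165 ± 51.0, and Gstm1, a glutathione transferase, went from 1996 ± 164 to 807 ± 43.6.

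In limma's model, 143 of 9967 genes changed in males, 57 higher and 86 lower. Of the called genes, 17 rose and 11 fell by at least 1 on the log2 scale. Among the 8 largest fitted increases, Myl10, a myosin light chain, had a log2 fold change of 3.48 ± 0.16 (SE; adjusted p = 1.1e-07). Thbs1 rose by 3.44 ± 0.46 (adjusted p = 0.00167), Itgam by 3.19 ± 0.37 (adjusted p = 0.000795) and Chad by 2.66 ± 0.24 (adjusted p = 8.82e-05). The others of these 8 were Creb5, Slc16a12, Gbp4 and Gbp11, at 2.64, 2.63, 2.37 and 2.23. Creb5 is a transcription factor, Slc16a12 a membrane transporter, and Gbp4 and Gbp11 are guanylate-binding proteins. Of the 8 largest decreases, clones aside, Nkg7 came first at -1.82 ± 0.27 (adjusted p = 0.00391). It was followed by Egr1 at -1.33 and Gstm1 at -1.30, then by Ndrg1, Gstm3, Galnt6, Pf4 and Flt3, which lay between -1.27 and -1.05. The oil levels of Thbs1, Itgam, Creb5 and Slc16a12 and the E2 levels of Nkg7 and Flt3 lay below the filter value of 182, close to background, so their fold changes are approximate. The count depended on single arrays. It was 77, 67 and 88 without male oil replicates 1, 2 and 3, then 85, 93 and 62 without male E2 replicates 1, 2 and 3, and 327 without female E2 replicate 1. Pf4 had an adjusted p of 0.0624 without male oil replicate 2 and 0.0503 without male E2 replicate 1, at -1.09 and -0.98. Galnt6 had one of up to 0.183, at -1.23 to -0.92, in 9 of the fits that left out 1 array, those without male oil replicates 1 to 3, male E2 replicates 1 and 3, female oil replicates 1 to 3 or female E2 replicate 2.

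By camera with the preset correlation, 13 of 28 fixed gene lists shifted in males, 6 upward and 7 downward, and 0 shifted with an estimated correlation, where the lowest adjusted p was 0.223. The S phase and DNA replication list had a median log2 fold change of 0.36, and all 38 of its members were above 0 (adjusted p = 2.91e-12; adjusted p = 0.293 with an estimated correlation). None of these 38 members passed over all genes in limma's test, and 2 passed adjusted over the list alone. The G2/M and mitosis list moved by 0.29 (adjusted p = 4.01e-12; 0.244 with an estimated correlation). The ribosome biogenesis list moved by 0.25 (adjusted p = 3.42e-10; 0.278 with an estimated correlation), with 0 members called over all genes and 8 higher adjusted over the list alone. Among the lists that moved downward, HSC identity had a median of -0.15 (adjusted p = 0.00133), TGF-beta signalling -0.17 (adjusted p = 0.00388) and the immediate early genes -0.18 (adjusted p = 0.00074), each with an adjusted p of 0.223 with an estimated correlation.

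The second comparison set E2 against oil in females. The same integrin chain, Itgam, rose from 183 ± 25.2 to 1204 ± 634 (mean ± SD, n = 3), and Thbs1 from 194 ± 92.1 to 1200 ± 758. Pf4, a chemokine of platelets and their precursors, fell from 838 ± 95.5 to 274 ± 79.5. Plek, a protein kinase C substrate of platelets and leukocytes, fell from 473 ± 65.8 to 154 ± 30.8. Gstm1 fell from 1871 ± 67.6 to 741 ± 71.4.

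In limma's model, 355 of 9967 genes changed in females, 81 higher and 274 lower. With each array centred on its median, the split was 45 higher and 358 lower, which moved the share of higher calls from 22.8% to 11.2%. The model pools 1 spread over all groups, while the female E2 arrays varied more than the others. Fitted on the compared groups alone, 67 genes were called in females and 390 in males, and array weights gave 226 and 409. The counts of 355 and 143 therefore do not show a larger response in females. Itgam rose by 2.57 ± 0.37 on the log2 scale (SE; adjusted p = 0.00301), Thbs1 by 2.48 ± 0.46 (adjusted p = 0.0117) and Chad by 1.55 ± 0.24 (adjusted p = 0.00407). The others of the 8 largest increases were Gbp11 at 1.65, Gbp4 at 1.64, Jdp2 at 1.45, Ppp2r2b at 1.43 and Slc16a12 at 1.18. Pf4 fell by 1.65 ± 0.20 (adjusted p = 0.000816) and Plek fell by 1.62 ± 0.16 (adjusted p = 0.000277). The other large decreases were in Nkg7, Gstm3, Gstm1, Ndrg1, Mdga1 and Egr1, from -1.51 to -1.27. The oil level of Ppp2r2b and the E2 levels of Plek, Nkg7, Gstm3 and Mdga1 lay below 182, so their fold changes are approximate. The count was 173, 115 and 119 without female oil replicates 1, 2 and 3, and 549 without female E2 replicate 1. Without female oil replicate 3 the adjusted p rose to 0.0604 for Thbs1, 0.0627 for Gbp4 and 0.0819 for Slc16a12, at 2.12, 1.49 and 1.00. Jdp2 passed narrowly (adjusted p = 0.0488) and did not pass without any 1 of male oil replicates 1 to 3, male E2 replicate 3, female oil replicates 1 to 3 or female E2 replicates 2 and 3, with values from 0.0687 to 0.168 and log2 fold changes within 1 SE (0.37) of that with all arrays.

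In females, 13 of 28 lists shifted by camera with the preset correlation, 4 upward and 9 downward, and 0 with an estimated correlation, where the lowest adjusted p was 0.31. The S phase list had a median of 0.28 (adjusted p = 3.12e-10; 0.388 with an estimated correlation), with 1 of 38 members called higher, Tk1. These cell cycle shifts rested largely on 1 array. Without female E2 replicate 1, the number of shifted lists was 6, and the S phase median was 0.08 (adjusted p = 0.00887). The G2/M list then moved from 0.14 to 0.02 (adjusted p = 0.126) and the ribosome biogenesis list from 0.15 to 0.02 (adjusted p = 0.157). The TGF-beta list stayed lower, at -0.25 with all arrays (adjusted p = 0.00203; 0.31 with an estimated correlation) and at -0.35 without that array (adjusted p = 0.00482).

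The third comparison averaged the E2 effect over the sexes, which doubles the arrays behind each value. Thbs1, Itgam and Chad rose, and the granule and platelet genes Nkg7 and Pf4 fell, together with the glutathione transferases Gstm1 and Gstm3. Genes of DNA replication such as Cdc6, Uhrf1 and Tk1 rose. Procr, the endothelial protein C receptor that marks HSCs, fell from 897 ± 22.4 to 595 ± 25.9 in males and from 739 ± 64.6 to 579 ± 42.4 in females (mean ± SD, n = 3). Egr1, an immediate early transcription factor, fell from 786 ± 198 to 310 ± 62.4 in males and from 1198 ± 78.4 to 502 ± 88.2 in females.

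In limma's model, 887 of 9967 genes changed on average, 311 higher and 576 lower. With each array centred on its median the split was 202 higher and 516 lower, which moved the share of higher calls from 35.1% to 28.1%. Among genes whose arrays did not overlap in both sexes, the largest increases were in Thbs1 at 2.96 ± 0.32 (SE; adjusted p = 0.000128), Itgam at 2.88 ± 0.26 (adjusted p = 2.89e-05), and Chad at 2.10 ± 0.17 (adjusted p = 1.28e-05). Myl10, Gbp4, Gbp11, Slc16a12 and Jdp2 followed, at 2.10, 2.00, 1.94, 1.90 and 1.28. Creb5 at 1.68 ± 0.21 (adjusted p = 0.000297), Ern1 at 1.34 ± 0.18 (adjusted p = 0.000492) and Arntl at 1.31 also rose more than Jdp2, but their female arrays overlapped. The largest decreases were in Nkg7 at -1.67 ± 0.19 (adjusted p = 0.000182), Pf4 at -1.40 ± 0.14 (adjusted p = 6.59e-05) and Gstm3 at -1.35 ± 0.11 (adjusted p = 1.34e-05). Plek, Gstm1, Egr1, Ndrg1 and Flt3 followed, from -1.33 to -1.10. The order and sizes are approximate where a group mean lay below 182, which held for Thbs1, Itgam, Slc16a12, Creb5 and Arntl in oil-treated males, for Nkg7 and Flt3 under E2 in both sexes, and for Plek and Gstm3 under E2 in females. The count fell to 539 without male oil replicate 2, 531 and 578 without male E2 replicates 2 and 3, and 476 and 567 without female oil replicates 2 and 3.

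**Figure D1:**
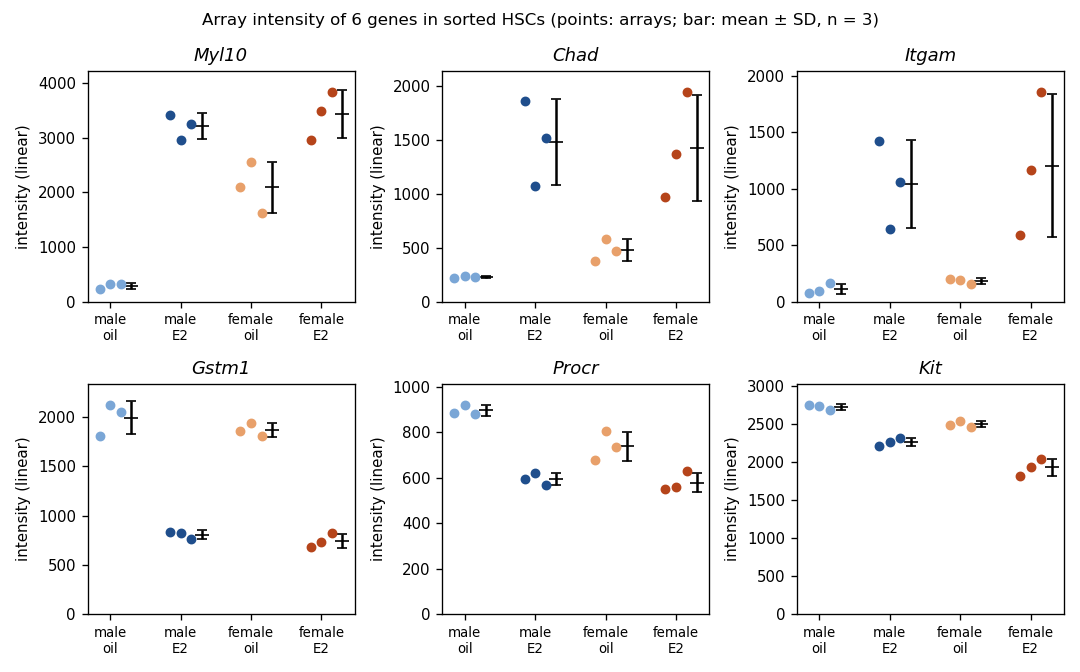
Linear array intensity of 6 genes (vertical axes from 0) in the 4 groups, with 1 point per array and bars for the mean ± SD (n = 3). Gstm1 lay near 1996 and 1871 under oil and near 807 and 741 under E2, while Myl10 was already at 2090 in oil-treated females.

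Lists of proliferation genes moved upward with E2. Of 38 S phase and DNA replication genes above the filter, 8 rose, 0 fell and 30 did not pass over all genes; 30 rose adjusted over the list alone. They included Cdc6 at 0.76 (adjusted p = 0.013) and Uhrf1 at 0.58 (adjusted p = 0.00911), which act in replication origin licensing and in maintaining DNA methylation, and the list's median was 0.33 (camera adjusted p = 2.78e-14; adjusted p = 0.258 with an estimated correlation). Of 41 G2/M genes, 4 rose, 0 fell and 37 did not pass, and 13 rose adjusted over the list alone. The 4 were Cdk1, the mitotic kinase, at 0.31 (adjusted p = 0.0152), Mad2l1 and Ndc80 at 0.33 and Nuf2 at 0.38. This list had a median of 0.22 (adjusted p = 8.01e-11; 0.258 with an estimated correlation). Of 31 ribosome biogenesis genes, 5 rose, among them Srm at 0.42 and Nop2 at 0.37, 0 fell and 26 did not pass; 12 rose adjusted over the list alone. Its median was 0.19 (adjusted p = 9.42e-09; 0.272 with an estimated correlation). Of 31 oxidative phosphorylation genes, Cycs rose at 0.38 (adjusted p = 0.0368) and 30 did not pass, with 0 adjusted over the list alone and a median of 0.09 (adjusted p = 3.7e-05; 0.258 with an estimated correlation).

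These proliferation values leaned on female E2 replicate 1. On that array the S phase list was 0.71 above the mean of the male oil arrays, while the mean of the 3 female E2 arrays was 0.27 ± 0.38 (SD). Without it the averaged medians were 0.23 for S phase (adjusted p = 5.38e-12), 0.15 for G2/M (adjusted p = 2.71e-08) and 0.15 for ribosome biogenesis (adjusted p = 2.74e-06), with 9 of 37, 3 of 41 and 3 of 31 members called higher. In an exact 2-sided permutation of the list means over 400 relabellings of treatment within sex, whose smallest p is 0.005, p was 0.02 for S phase (adjusted p = 0.035), 0.01 for G2/M (adjusted p = 0.0215) and 0.02 for ribosome biogenesis (adjusted p = 0.035).

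Lists of stem cell identity, of cell cycle inhibitors, G1 cyclins and quiescence, and of signalling moved downward with E2. Of 35 HSC identity genes, 3 rose, 11 fell and 21 did not pass over all genes; 4 rose and 16 fell adjusted over the list alone. Procr fell by 0.47 ± 0.06 (adjusted p = 0.000537), Robo4, a receptor that holds HSCs in the marrow, fell by 0.52 (adjusted p = 0.00226), and the transcription factor Gata2 fell by 0.38 (adjusted p = 0.0053), while Trpc6, a calcium channel, rose by 0.78 (adjusted p = 0.00226). The list's median was -0.13 (camera adjusted p = 0.00382; adjusted p = 0.258 with an estimated correlation). Of 18 genes of CDK inhibitors, G1 cyclins and quiescence, 0 rose, 5 fell and 13 did not pass; 2 rose and 9 fell adjusted over the list alone. Those that fell included Egr1, the cell cycle kinase gene Cdk6 at -0.67 (adjusted p = 0.00106) and Foxo3 at -0.25 (adjusted p = 0.0475), and the median was -0.16 (adjusted p = 0.0149; 0.258 with an estimated correlation). This list holds both inhibitors and drivers of the cell cycle, so its fall alone does not show a change in quiescence. Of 20 immediate early and stress genes, 8 fell and 12 did not pass, with 8 also adjusted over the list alone. They included Ier2 at -0.72, Ier3 at -0.65 and Zfp36 at -0.46, and the median was -0.11 (adjusted p = 0.0023; 0.258 with an estimated correlation). Of 13 TGF-beta signalling genes, 4 fell and 9 did not pass, with 7 lower adjusted over the list alone. The 4 were the receptor gene Tgfbr2 at -0.57 (adjusted p = 0.00831), Smad7 at -0.39, Ltbp3 at -0.36 and Smad3 at -0.34, and the median was -0.17 (adjusted p = 0.000737; 0.258 with an estimated correlation). Of 16 adhesion and homing genes, Robo4 and Esam fell and 14 did not pass, with 3 lower adjusted over the list alone and a median of -0.12 (adjusted p = 0.0458; 0.258 with an estimated correlation). That last call ended, with adjusted p from 0.0589 to 0.097, without any 1 of male oil replicates 2 and 3, male E2 replicates 2 and 3, female oil replicates 1 and 2, or female E2 replicates 1 and 2. In the exact permutation of list means the first 4 of these lists had an adjusted p of 0.014 each and the adhesion list 0.0215. By fry the adjusted p was 0.0011, 0.00057, 0.00404, 0.00117 and 0.00891, in the order given here.

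**Figure D2:**
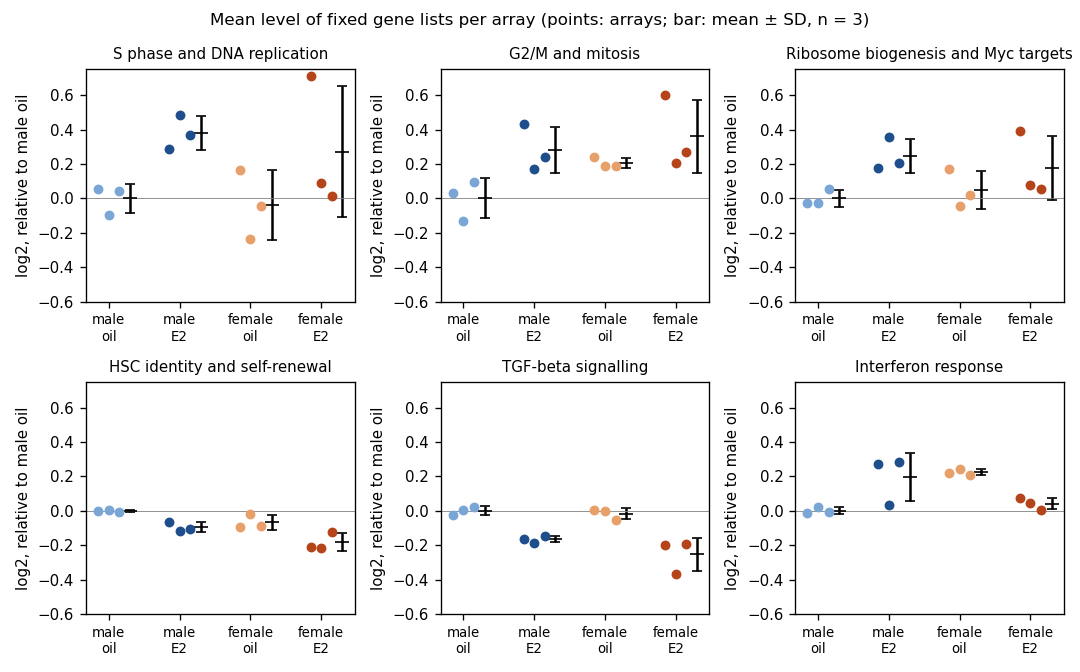
Mean log2 level of 6 fixed gene lists per array, relative to the mean of the male oil arrays, with 1 point per array and bars for the mean ± SD (n = 3). Female E2 replicate 1 stands at 0.71 in the S phase list, while the interferon list lies at 0.20 in E2-treated males and 0.22 in oil-treated females.

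Of 7 markers of megakaryocytes, the platelet precursors, that lay above the filter, Plek, Pf4, the platelet glycoprotein gene Gp5 at -0.77 and the integrin gene Itga2b at -0.44 fell, Gp9 rose at 0.51 (adjusted p = 0.0187), and 2 did not pass; 2 rose and 4 fell adjusted over the list alone. The median was -0.44 (camera adjusted p = 0.0241; adjusted p = 0.258 with an estimated correlation), and without female E2 replicate 1 the list did not pass (adjusted p = 0.0729). Of 5 genes of multipotent and myeloid progenitors, the cytokine receptor gene Flt3, Satb1 at -0.35 and Cd34 at -0.29 fell, 2 did not pass, 3 were lower adjusted over the list alone, and the median was -0.37 (adjusted p = 0.00235; 0.258 with an estimated correlation). In the exact permutation of list means the progenitor list did not pass (adjusted p = 0.0659), and its E2 and oil arrays overlapped in both sexes. The megakaryocyte list had an adjusted p of 0.014 there. None of the other 8 marker lists passed by camera. The granulocyte list had a median of -0.29 over 9 genes (adjusted p = 0.146), with Prtn3 lower. The T and NK cell list had a median of -0.84 over 2 genes (adjusted p = 0.087), with Nkg7 lower. Over 3 genes each, the erythroid list had an adjusted p of 0.144 with Tfrc higher, and the dendritic list one of 0.389 with Flt3 lower. The stroma list had one of 0.503 over 4 genes, with Col1a2 higher at 0.90. Col1a2 under oil and Satb1 under E2 lay below 182, so their sizes are approximate. The monocyte, B cell and mast cell lists held 1 gene each above the filter, Cd68, Cd79b and Gata2, with adjusted p of 0.607, 0.106 and 0.0579 and log2 fold changes of 0.12, -0.41 and -0.38.

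The list of estrogen-responsive genes did not shift in 1 direction in these cells, but members changed both ways. Of 20 estrogen-responsive genes, Sgk1, a kinase gene, rose by 0.90 ± 0.21 (adjusted p = 0.0189), Igfbp4 fell by 0.30 (adjusted p = 0.0246) and 18 did not pass; 2 rose and 4 fell adjusted over the list alone. The list's median was 0.01 (camera adjusted p = 0.854). Fry's test for changes in either direction gave an adjusted p of 9.26e-08, so the median near 0 does not mean that the members were unchanged. That test does not compare the list with other genes, of which 887 of 9967 were called. It was also small for other lists, at 1.93e-09 for HSC identity and 1.65e-06 for glycolysis. A change particular to estrogen-responsive genes is therefore not shown. The receptor gene Esr1 was at -0.34 ± 0.12 and did not pass (adjusted p = 0.0965). Greb1 and Pgr, targets of the receptor in reproductive tissue, and the second receptor gene Esr2 lay below the filter. Without the filter, Greb1 rose by 1.03 ± 0.19 (adjusted p = 0.0092), from 63.5 to 113 in males and from 62.2 to 160 in females. These levels of Greb1 and the oil levels of Sgk1 lay below 182, so the sizes of both rises are approximate. Pgr was at 0.53 ± 0.14 (adjusted p = 0.0676) and Esr2 at 0.00 (adjusted p = 0.996). Ccnd1, Myc, Mki67 and Cdkn1c did not pass, at 0.30, -0.07, 0.18 and -0.08 (adjusted p = 0.0988, 0.628, 0.286 and 0.52). Cdkn1a and Ddx3y were not analysed here.

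The surface proteins of the sort gate bound which cells were collected, so their transcripts are no finding on their own. Kit fell by 0.32 ± 0.05 on average (adjusted p = 0.0023), while Slamf1 at -0.27 (adjusted p = 0.225) and Cd48 at -0.27 without the filter (adjusted p = 0.411) did not pass. In females alone Kit was lower at -0.37 (adjusted p = 0.0166) and Procr at -0.35 (adjusted p = 0.0462). With single arrays left out the sizes stayed similar while the adjusted p passed 0.05. Kit had 0.0543, 0.0796 and 0.0567 without female oil replicates 1, 2 and 3, at -0.37, -0.36 and -0.38. Procr had one of up to 0.202, at -0.41 to -0.29, in 11 of the 12 fits that left out 1 array, all but the one without female E2 replicate 3.

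The responses of males and females ran together across genes. Pearson's r between the log2 fold changes of the sexes was 0.63 and Spearman's rho 0.50 over 9967 genes, which are not independent replicates. With 1 array left out, r ranged from 0.521 to 0.647. Of the called genes, 24 rose in both sexes and 66 fell in both. If the calls were independent, 0.463 and 2.36 would be met by chance. They are not independent, since both use the same estimate of each gene's spread. In 379 of the 408 genes called in either sex (92.9%) the sign was the same, and 0 genes were called in opposite directions by limma.

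**Figure D3:**
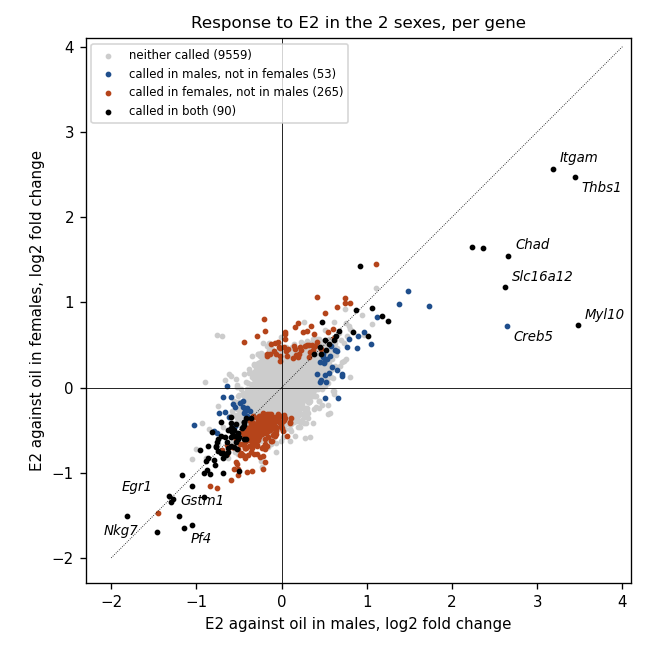
Log2 fold change with E2 in females (vertical axis) against that in males (horizontal axis), with 1 point per gene and the dotted line marking equal responses. Itgam, Thbs1 and Chad lie high in both sexes, and Myl10 lies far to the right, at 3.48 in males and 0.73 in females.

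The next comparison asked whether the response to E2 differed between the sexes. Myl10 rose from 290 ± 50.5 to 3211 ± 233 in males and from 2090 ± 464 to 3428 ± 439 in females (mean ± SD, n = 3). The difference of the responses, female minus male, was -2.75 ± 0.23 on the log2 scale (SE; adjusted p = 0.000181). This was the 1 gene of 9967 called by limma, while 535 had an unadjusted p under 0.05. Of the other genes with the smallest p, Pamr1 at 0.89 ± 0.16 and Rnf121 at 0.97 ± 0.17 had an adjusted p of 0.239. Creb5 at -1.92 ± 0.41, Cux1 at -0.57 and Shroom4 at 0.55 had one of 0.591. Except for Cux1, each of these 5 genes had a group mean below 182, as did Creb5 in oil-treated males at 103, so their sizes are approximate. Without female E2 replicate 1 the count was 2. Relabelling sex within treatment gave counts as large in 8 of 100 draws. Such relabelling can turn genes that differ between the sexes, such as Xist, into apparent differences of response. It therefore cannot decide whether the count is within what chance gives.

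Among the lists, the interferon response differed between the sexes. Its median difference was -0.37, and 24 of 24 members lay below 0 (camera adjusted p = 5.48e-12; adjusted p = 0.144 with an estimated correlation). Over all genes 0 members were called by limma, and 8 were lower adjusted over the list alone. With E2, the list's median was 0.19 in males (adjusted p = 4.15e-05; 0.223 with an estimated correlation) and -0.18 in females (adjusted p = 0.0116; 0.388 with an estimated correlation). The exact 2-sided permutation of sex within treatment gave p = 0.015 for the mean difference and 0.42 after adjustment over the lists. It also scrambles sex differences shared by both treatments, so it is not a test of the difference of responses alone. Without female E2 replicate 1, 6 lists differed, among them S phase at -0.27 and G2/M at -0.24 (both adjusted p = 3.35e-05) and ribosome biogenesis at -0.25 (adjusted p = 6.12e-05).

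The last comparisons set females against males under each treatment. Xist was higher in females by 5.69 ± 0.09 under oil (adjusted p = 1e-13) and by 5.68 under E2 (adjusted p = 1.02e-13). Under oil, Myl10 was also higher in females by 2.83 ± 0.16 (adjusted p = 7.68e-07), the transcription factor gene Creb5 by 2.14 ± 0.29 (adjusted p = 0.0153) and the transporter gene Slc16a12 by 1.66 ± 0.23 (adjusted p = 0.0171). Under E2, Myl10 differed by 0.09 and did not pass (adjusted p = 0.903). Without the filter, Eif2s3y, Kdm5d and Uty were lower in females under oil by limma, at -4.44, -3.71 and -3.75. The lower group of these 3 genes, of Xist, and of Creb5 and Slc16a12 under oil lay below 182, at or near background, so the sizes of these differences are approximate.

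Under oil, limma called 4 of 9967 genes, all higher in females, and 497 had an unadjusted p under 0.05. Creb5 had an adjusted p of 0.0613 to 0.12, at 2.07 to 2.26, without any 1 of male oil replicates 1 to 3 or female oil replicate 1. Slc16a12 had one of 0.107 to 0.169, with differences within 1 SE of that with all arrays, without any 1 of male oil replicates 1 and 3 or female oil replicates 1 and 2. The count was 2 without male oil replicate 1 or female oil replicate 1, and 8 without female E2 replicate 1. Under E2, limma called 1 gene, Xist, and 901 had an unadjusted p under 0.05. That count was 17 without female E2 replicate 1, and 2 without male E2 replicate 2, female oil replicate 2 or female E2 replicate 3.

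By camera, 7 of 28 lists differed between the sexes under oil and 4 under E2. With an estimated correlation 2 remained under each. Genes escaping X inactivation were higher in females, with a median of 0.42 under oil (adjusted p = 3.89e-14; 0.004 with an estimated correlation) and 0.28 under E2 (adjusted p = 1.51e-09; 0.0151 with an estimated correlation). Of these 7 genes, Xist was called over all genes under each treatment, and 4 were higher adjusted over the list alone. Kdm6a at 0.48, Eif2s3x at 0.47 and Kdm5c at 0.42 did not pass over all genes under oil. Immediate early genes were higher in females under oil at 0.21 (adjusted p = 2.04e-08; 0.0454 with an estimated correlation) and under E2 at 0.24 (adjusted p = 4.42e-09; 0.0324 with an estimated correlation), with 0 of 20 called over all genes and 5 and 8 higher adjusted over the list alone. The G2/M list was higher in females under oil at 0.21 and under E2 at 0.09 (adjusted p = 2.69e-13 and 0.000549; 0.382 and 0.655 with an estimated correlation). The interferon list was higher in females under oil at 0.17 and lower under E2 at -0.16 (adjusted p = 8.63e-10 and 0.00225; 0.0926 and 0.655 with an estimated correlation). Under oil, the unfolded protein response and cholesterol lists were also higher in females, at 0.12 and 0.13, and the HSC identity list was lower, at -0.08 (adjusted p = 4.96e-06, 0.00417 and 0.00228; 0.217, 0.564 and 0.217 with an estimated correlation). The Y-linked list held 2 genes above the filter, Uba1y and Sry. It did not differ between the sexes, at -0.06 under oil and -0.10 under E2 (adjusted p = 0.872 and 0.603). These 2 genes thus did not separate males from females as Eif2s3y, Kdm5d and Uty did. In the averaged E2 comparison neither the Y-linked list (adjusted p = 0.689) nor the list of genes escaping X inactivation (adjusted p = 0.389) passed.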

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

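Chosen only after the results were seen were the tests of array saturation and of a raised baseline for Myl10 and all tests of cell admixture, while the tests that leave out 1 array or regroup the arrays were set out before their values were known. The permutation of the interferon list was also added after camera's results had been seen.

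The response of Myl10 to E2 differed between the sexes by -2.75 on the log2 scale, female minus male, which is why it is listed here. Array saturation is argued against, since the mean level in E2-treated females lay at percentile 97.7 of the probe sets. A single deviating array is also argued against, since the highest adjusted p with 1 array left out was 0.00156. The female minus male difference under E2 was 3.12% of that under oil, which describes where the groups differed and explains nothing further. Why oil-treated females were higher was not tested, and a biological difference between the sexes stays open.

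The interferon response list is here because its median difference of the E2 response between the sexes was -0.37. A single deviating array is argued against, since the mean difference stayed at -0.34 or further from 0 with any 1 array left out. A chance division of the arrays stays open: the list was picked as the most shifted of 28, the exact permutation p was 0.015 unadjusted and 0.42 adjusted over the lists, and camera gave 0.144 with an estimated correlation. The mean of the list was 0.20 higher with E2 in males and fell by 0.18 in females, and females were 0.22 higher under oil. A difference between the sexes and a difference in the handling of the 4 groups, whose dates the labels do not give, also stay open.

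Itgam, Thbs1, Gbp4 and Gbp11 rose together with E2, and Itgam is a gene of mature myeloid cells, which the lineage gate would remove. Granulocytes as the source of a rise as large as that of Itgam are argued against, since their 12 markers, dim ones included, had a median of -0.30. In all, 12 of 12 lay below 0 and 0 were called by limma. The 9 above the filter vary together (estimated correlation 0.76), so these signs are not separate observations. The mean of those 9 had SDs of 0.44 to 0.85 within groups, and the exact permutation p of its averaged E2 effect was 0.39. Without female E2 replicate 1 their median was -0.12 on average and 0.05 in females. The abundant S100a8 stood at 4007 and 3394 and S100a9 at 3453 and 3051 in males under oil and E2. The 8 markers of megakaryocytes had a median of -0.56, although Gp9 rose. Several were already well above the filter under oil, with Pf4 at 894, Itga2b at 659 and Gp5 at 574 in males. A fall of these transcripts within the HSCs could hide an admixture, so megakaryocytes or platelets are not excluded. For granulocytes and monocytes together the median over 22 markers was -0.25, but the bound set for this test was not met because Ccr2 was called higher at 0.58 (adjusted p = 0.0449), and granulocytes were split off after that was seen. The 10 monocyte markers alone had a median of -0.052, from -0.39 to 0.58, far under the 2.88 of Itgam, but 9 of them lay below the filter near background, so monocytes are not excluded, and a response of the HSCs themselves stays open too.

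Probe sets that the comparisons of genes did not use also responded. With E2 averaged over the sexes, 39 probe sets with several gene symbols were called by limma, 17 higher and 22 lower, of 833 above the filter. Of 3667 probe sets with no symbol, 13 were called, 3 higher and 10 lower.

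Regrouped arrays gave the following counts. For E2 averaged over the sexes, the real grouping called 887 genes and the highest of the other relabellings 2. Only the real grouping, 1 of 100, was as large, so a chance division of the arrays is argued against. A difference in handling between the oil and E2 groups is not tested by this. For the difference of responses, the real count of 1 was met by 8 of 100 relabellings and the highest was 4. These relabellings can also turn sex differences such as that of Xist into differences of response. They therefore cannot decide on chance for that count. For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. E2 in males called 143 genes against a highest other of 0, and E2 in females 355 against 0, each the 1 split as large. Females against males gave 4 against 0 under oil, and under E2 1 against 5, where 2 of the 10 splits gave as many.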

How the results depend on the processing

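The exact permutation of list means was the 1 test here chosen after the results were seen. Where a value moved, the cause was not tested unless one is given.

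Under quantile normalization, median centring, an offset of 16, averaged probe sets, and eBayes with trend, the counts of genes in all 6 comparisons stayed within 1.5 times in total, and no result changed direction, although median centring took the genes higher on average from 311 to 202 and those higher in females from 81 to 45. Some named calls ended. Under quantile normalization Jdp2 and Procr in females had adjusted p of 0.0527 and 0.0691. With eBayes with trend Jdp2 had 0.101 and Galnt6 in males 0.0612. Median centring gave Galnt6 0.0531, and array weights gave Procr 0.0842. Without the filter, where more genes share the adjustment, the counts were 80 in males, 183 in females, 568 for the average, 7 between the sexes under oil and 4 under E2. The filter at the 25th percentile gave 3 under E2. Array weights gave 409 in males, 226 in females and 7 under oil, and a fit of the compared groups alone gave 390, 67 and 7. The spread of the female E2 arrays bears on these, since the SD of log2 differences between replicates was 0.311 there and 0.180 to 0.211 in the other groups, and their weights were 0.326 to 0.664 against 0.879 to 2.10. A log2 fold change of at least 1 left 28 genes in males, 29 in females and 30 for the average, and an adjusted p of 0.1 gave 264, 657 and 1459, both by construction.

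With 1 array left out, the counts ranged from 62 to 327 in males, 115 to 549 in females, 476 to 1147 for the average, 1 to 2 for the difference of responses, 2 to 8 between the sexes under oil and 1 to 17 under E2. Leaving out female E2 replicate 1 gave the highest value except for the average, whose highest came without female E2 replicate 3. The numbers of shifted lists ranged from 12 to 14, 6 to 14, 10 to 14, 1 to 6, 6 to 11 and 3 to 7 in the same order, and r between the sexes from 0.521 to 0.647.

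With an estimated correlation, 0 lists shifted in males, in females, for the average and for the difference of responses, and 2 under oil and 2 under E2. Fry gave 1 under oil and 1 under E2. Without the filter 4 lists differed in response, 12 under oil and 9 under E2. Quantile normalization gave 2 and array weights 3 for the difference of responses. The exact permutation gave 0 for the difference of responses and 16 for the average. Agreement of the sexes moved from 0.63 to 0.45 without the filter, and Spearman's rho was 0.50.

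Replicate numbers did not pair the arrays, with correlations between arrays of the same number in different groups from -0.26 to 0.20 and 0 of 12 arrays closest to their own number. With a block for the number, 103, 258, 736, 1, 3 and 1 genes were called, of which 101, 244, 704, 1, 3 and 1 were among those without it. Slc16a12 under oil (adjusted p = 0.0692), Galnt6 in males (0.0782), and Jdp2 (0.0766) and Procr (0.0664) in females then did not pass, with the same log2 fold changes.

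Calls were counted over the genes named by size, by p or in advance, some of which were not called. Genes named only as list members were left out. Also left out were the changed filters and thresholds and the fit of the compared groups alone. In males, 457 of the counted alternative values stayed called or stayed not called, 14 lost a call and 3 gained one. These numbers were 435, 32 and 2 in females and 471, 0 and 3 for the average. Among the genes left out, some averaged calls by limma ended without the filter. They were Satb1 and Cd34 (adjusted p = 0.0664 each), Prtn3 (0.0789) and Tfrc (0.11). Array signal over background limits genes such as Greb1 and Esr2, whose group means lay between 62.2 and 160, below the filter value of 182.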

Other observations

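The tests of oil-treated females against the E2 response, the covariance included, were chosen after the results were seen.

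Of 24 genes of the unfolded protein response, 3 rose with E2 averaged over the sexes, Ern1, a sensor of misfolded protein, at 1.34 ± 0.18 (SE; adjusted p = 0.000492), Sdf2l1 at 0.51 and Manf at 0.32. Herpud1 fell by 0.27, 20 did not pass, and 4 rose and 1 fell adjusted over the list alone. The list's median was 0.12 (camera adjusted p = 0.00447; adjusted p = 0.258 with an estimated correlation). Of 16 glycolysis genes, Vegfa at 0.74 and Pgk1 at 0.29 rose, Aldoc at -0.56, Slc2a3 at -0.38 and Bnip3 at -0.23 fell, and the median was 0.02 (adjusted p = 0.503).

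Of 15 genes of cholesterol biosynthesis, Insig1 fell by 0.58 (adjusted p = 0.012) and 14 did not pass, with a median of -0.13 (camera adjusted p = 0.151). In females alone the list moved by -0.24 (adjusted p = 0.0203; 0.427 with an estimated correlation). Of 8 p53 targets, Trp53inp1 fell by 0.62 (adjusted p = 0.00123), 7 did not pass, and the median was -0.09 (adjusted p = 0.087). The 23 ribosomal protein genes had a median of 0.00 (adjusted p = 0.726), and 0 were called by limma.

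Myl10, Creb5 and Slc16a12, the 3 genes besides Xist called higher in oil-treated females than in oil-treated males, were all called higher with E2 in males, where 0.0172 would be met by chance if the lists were independent. The lists are not independent, since both comparisons use the male oil arrays. The 81 genes called higher with E2 in females differed between the sexes under oil by a median of -0.037, with quartiles from -0.21 to 0.11. These genes were chosen against the same female oil arrays, which pulls this median down, so whether the E2 response was already present in oil-treated females stays open. Across genes, the covariance of the sex difference under oil was 0.0126 with the E2 response of males and -0.0034 with that of females. In 100 simulations with no shared effect and each group's own spread, it ranged from 0.00683 to 0.00826 and from -0.00725 to -0.00561, so both observed values lay above the range. The simulated genes were independent, which makes the range too narrow, so a shared effect stays open. Whether endogenous estrogen accounts for the 3 genes was not analysed here.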
